A study of Yarrowia lipolytica with 11 samples.

How the data were processed

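RNA sequencing was used to measure transcript levels in the oleaginous yeast Yarrowia lipolytica. Per the labels, a wild type and a mutant were grown in the absence and in the presence of hexanoic acid at 1 g/L, a medium-chain fatty acid. The mutant carries a deletion of PEX10, a gene needed to assemble peroxisomes, and a plasmid that overexpresses DGA1, which encodes a diacylglycerol acyltransferase of storage lipid synthesis. Per the labels' protocols, cultures came from separate colonies in YPC medium and were collected in exponential phase, RNA was extracted with TRI Reagent, and directional libraries (NEBNext Ultra II) were sequenced on an Illumina NovaSeq instrument. There were 11 libraries: 3 of the untreated wild type, 3 of the wild type with hexanoic acid, 2 of the untreated mutant and 3 of the mutant with hexanoic acid.

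The submitters' processing notes name FastQC 0.11.7, STAR 2.7.9a, SAMtools 1.9, HTSeq 0.11.0 and DESeq2 1.32.0. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical gene copies, are therefore not separated here. The deposited counts are whole numbers of reads per gene for each library, with 7135 genes identified by locus tag or, for mitochondrial and noncoding genes, by name. The deposited normalized values are a signal equal to those counts divided by 1 size factor per library, as tested on the values of the tables. All tests used the raw counts, and the normalized values served as an alternative for PEX10 and DGA1.

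Library totals ran from 9988288 to 17519857 counts. Levels are given as CPM, counts scaled to a common library size. Correlations of log2 CPM between libraries of 1 group were 0.965 to 0.989 in the untreated wild type, 0.980 to 0.985 in the wild type with hexanoic acid, 0.956 in the untreated mutant and 0.974 to 0.990 in the mutant with hexanoic acid. In a chi-square comparison of counts between libraries of 1 group, the smallest value per degree of freedom was 39.48, far above the sampling noise of a library sequenced again, so each library counted as 1 replicate. The common biological coefficient of variation was 23.8%.

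Counts were analysed in R 4.3.3 with edgeR 4.0.16 (limma 3.58.1). Libraries were scaled by TMM, and genes were kept by filterByExpr on the 4 groups, which left 6301 genes and removed 834. One mean per group was fitted to all 11 libraries, so that the group of 2 libraries shared the estimate of the spread. Each comparison used the quasi-likelihood F test with robust=TRUE and Benjamini-Hochberg adjusted p under 0.05. The 5 comparisons were hexanoic acid in the wild type, hexanoic acid in the mutant, mutant against wild type without and with hexanoic acid, and the difference between the responses of both strains. A log2 fold change is given ± its standard error, which is the absolute log2 fold change divided by the square root of F. CPM values are TMM-scaled and given ± SD. In simulated data with 200 changed genes, the test recovered 51% of 2-fold and 94% of 4-fold changes for hexanoic acid in the wild type, 35% and 88% in the mutant, 38% and 89% for mutant against wild type without acid, 54% and 98% with acid, and 7% and 74% for the response difference. False calls made up 7.64%, 5.38%, 3.05%, 5% and 3.57% of the calls in the same order. Recovery under this adjustment depends on how many genes change, and more than 200 genes passed in each real comparison. These shares are therefore not the sensitivity of the real comparisons.

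The tables hold locus tags and no names for nuclear genes, and none of the tags matched the reference table of gene symbols used here (0 matches). Gene names in the text were paired with tags from published assignments known beforehand, without a reference table to test them, which limits every statement about a named gene. As a check on them, 7 pairs of partner subunits had a median correlation of 0.982 over the 11 libraries, higher than in all 10000 random sets of pairs (0% as high), and a median log2 level difference of 0.744, which 2.89% of random sets matched or undercut. Single pairs went lower, with r = 0.374 for SDH1 and SDH2 (0.924 within groups) and 0.684 for PXA1 and PXA2 (−0.242 within groups). Within groups r was also low for KGD1 and KGD2 (0.424) and LSC1 and LSC2 (0.598). It was 0.845 for FAS1 and FAS2, 0.927 for ACL1 and ACL2 and 0.871 for IDH1 and IDH2. Differences between the groups enter the values over 11 libraries, and the check does not cover every name. Of 148 listed locus tags, 146 were in the tables. The tags listed as URA3 and XPR2 were not analysed here, and 12 lists defined by words in gene descriptions were not built because no descriptions were used here.

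The comparisons, the gene names and lists, the rule for named genes and the alternatives were chosen before the data were examined. The lists covered peroxisomal beta-oxidation, acyl-CoA ligases, peroxins other than PEX10, the glyoxylate cycle and gluconeogenesis, the TCA cycle, glycolysis and hexose uptake, the pentose phosphate pathway and NADPH supply, fatty acid synthesis, glycerolipid assembly, lipases, alkane and fatty alcohol oxidation, mevalonate and ergosterol synthesis, regulators, and mitochondrially encoded genes. These 14 lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. In simulated data, 1 of 1 shifted list was recovered and 0 of 13 unchanged lists were called. The simulated genes varied independently, so this run could not test false calls from genes that vary together. In the real data the estimated correlation of the TCA cycle list was 0.326 for hexanoic acid in the wild type. Named genes are PEX10 and DGA1, up to 4 members of each list with the smallest p in a comparison, and the genes of at least 10 mean CPM with the largest rises and falls whose libraries did not overlap between groups. For the response difference no such condition on overlap was set. Some were left out for length, and a gene named outside this rule is said to be so.

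Alternatives were DESeq2 size factors, scaling by total count only, no filter and a stricter filter (mean CPM of at least 10), robust=FALSE, DESeq2 1.42.0, a fit to only the 2 groups compared, a replicate block by either numbering of the labels, an estimated inter-gene correlation, and leaving out each library in turn. Where a library is left out of the untreated mutant, its remaining library is assumed to vary like the other groups. Intervals and tests cover the spread between these cultures, and counts of reads without molecular identifiers are not independent molecules.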

Results

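The data comprised 11 RNA-seq libraries in a design of 2 strains by 2 conditions. The untreated wild type had 12889478, 15322935 and 17519857 counts in its 3 libraries, and the wild type with 1 g/L hexanoic acid had 12753299, 9988288 and 14698252. The untreated mutant had 13170304 and 14348456 counts in its 2 libraries, and the mutant with hexanoic acid had 12787936, 14428906 and 12936329 in 3. The first principal component of the log2 CPM values held 66.9% of the variance. Untreated wild-type libraries lay between −82.77 and −71.1 on it, all 6 libraries with hexanoic acid between 37.03 and 42.03, and the untreated mutant libraries at −14.8 and 7.95. The second component (11.4%) separated the strains within each condition.

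**Figure D1:**
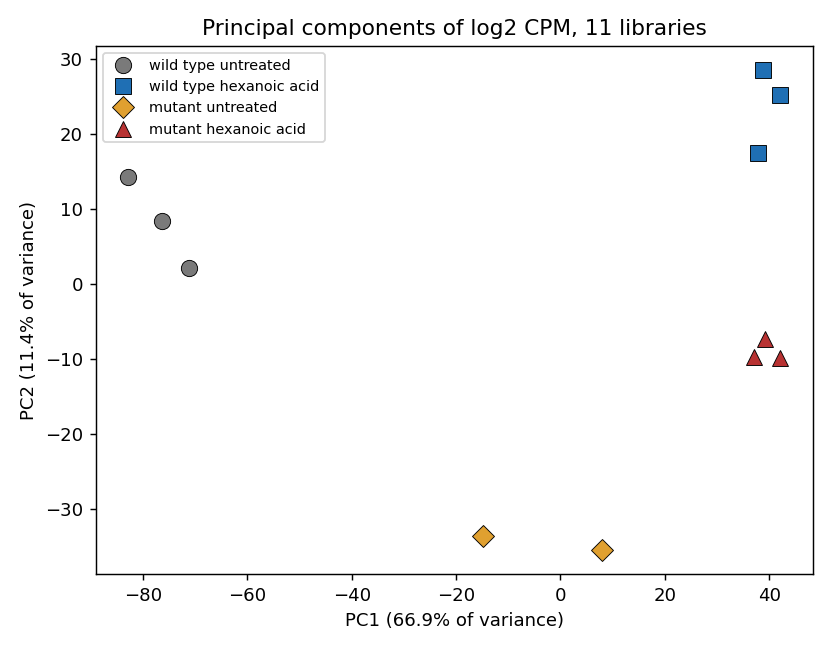
Each of the 11 libraries is placed by its scores on the first principal component (x axis, 66.9% of variance) and the second (y axis, 11.4%) of log2 CPM, with 1 symbol per group. Libraries with hexanoic acid from both strains lie between 37.03 and 42.03 on the x axis, and the 2 untreated mutant libraries lie between them and the untreated wild type.

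The genes altered in the mutant were examined first. PEX10 (YALI0_C01023g) was at 15.5 ± 4.38 CPM (SD, n = 3) in the untreated wild type and 6.18 ± 1.66 CPM (n = 2) in the untreated mutant. With hexanoic acid it was at 14.0 ± 4.09 CPM in the wild type and 6.33 ± 1.49 CPM in the mutant (n = 3 each). The highest mutant library had 8.04 CPM and the lowest wild-type library 10.7 CPM. The log2 difference was −1.32 ± 0.34 without acid (adjusted p = 0.00963) and −1.15 ± 0.29 with acid (adjusted p = 0.0330, edgeR). Mutant libraries still held 66 to 123 PEX10 reads, and the level was 39.98% of the wild type without acid and 45.2% with acid. The PEX10 call without acid was lost when mutant replicate 1 was left out (−1.08, adjusted p = 0.0712). The call with acid was lost without mutant replicates 1 (−1.06), 2 (−1.36) or 3 (−1.04) and without wild-type replicates 1 (−0.89) or 3 (−1.21), with adjusted p from 0.0576 to 0.123 in these fits. DGA1 (YALI0_E32769g) was at 3252 ± 44.6 CPM in the untreated mutant against 188.0 ± 37.5 in the wild type, a log2 difference of 4.11 ± 0.40. With hexanoic acid its levels were 4743 ± 2660 and 134.9 ± 33.7 CPM, a log2 difference of 5.14 ± 0.41. Counts per gene do not separate the chromosomal copy of DGA1 from the plasmid copy.

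**Figure D2:**
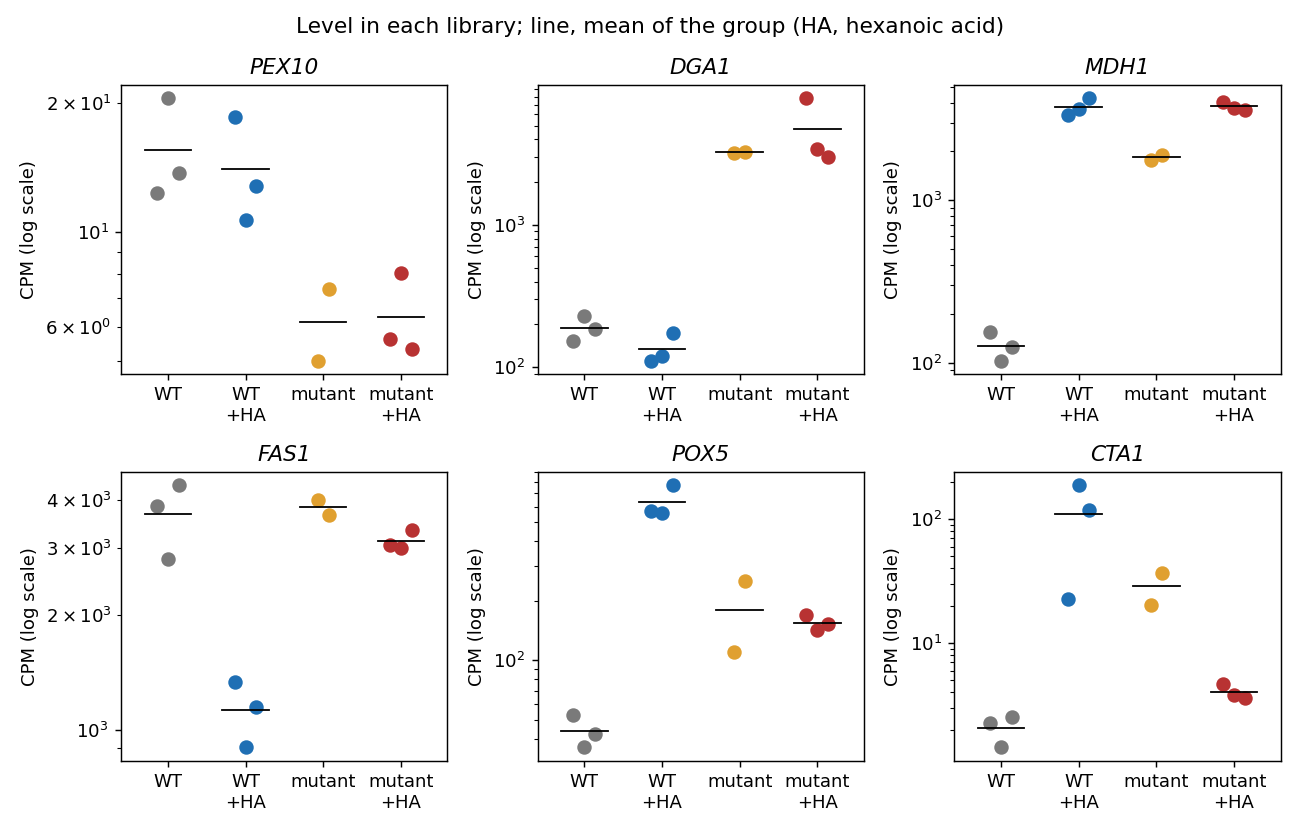
CPM on a log axis in each library (points) with the group mean (line) for 6 genes in the wild type (WT) and the mutant, without and with hexanoic acid (HA). MDH1 in the untreated mutant, at 1776 to 1911 CPM, lies between the untreated wild type and both groups with acid, while FAS1 falls to 902 to 1335 CPM only in the wild type with acid.

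The first comparison asked how the wild type responds to hexanoic acid. Most listed genes of the TCA cycle, of peroxisomal beta-oxidation and of the glyoxylate cycle and gluconeogenesis rose, and most of fatty acid synthesis fell. MDH1 (YALI0_D16753g), listed as mitochondrial malate dehydrogenase, went from 127.3 ± 26.1 to 3761 ± 460 CPM (n = 3 each), a 29.6-fold rise. CIT2 (YALI0_E02684g), a citrate synthase, rose 21.6-fold, and MAE1 (YALI0_E18634g), malic enzyme, rose 51.8-fold from 13.1 ± 1.12 to 677.4 ± 111 CPM. FAS1 (YALI0_B15059g), a fatty acid synthase subunit, fell from 3688 ± 810 to 1131 ± 218 CPM.

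In the TCA cycle list, 9 of 12 genes rose and 1 fell in the wild type, with 10 passing adjusted over the list alone. Log2 changes were 4.89 ± 0.24 for MDH1, 3.17 ± 0.25 for CIT1 (citrate synthase), 2.72 ± 0.21 for IDH2 (isocitrate dehydrogenase) and 2.36 ± 0.17 for LSC2 (succinyl-CoA ligase), and the gene that fell was SDH1 (succinate dehydrogenase, −0.67 ± 0.23). The list passed camera at the preset correlation (adjusted p = 3.91e-06) and not with an estimated one (0.506), as was the case for the beta-oxidation, glyoxylate and fatty acid synthesis lists (0.506 each). In the beta-oxidation list, 10 of 12 genes rose and none fell, with 10 passing adjusted over the list alone (camera adjusted p = 0.00139). Acyl-CoA oxidases POX5 and POX3 changed by 3.85 ± 0.31 and 2.11 ± 0.24, the multifunctional enzyme MFE1 by 2.16 ± 0.22, and CTA1, listed as a catalase, by 5.72 ± 0.68. CTA1 varied from 22.8 to 189.1 CPM among the treated wild-type libraries. In the glyoxylate and gluconeogenesis list, 7 of 10 genes rose and 2 fell, 9 adjusted over the list alone (camera adjusted p = 0.0172). Its members CIT2, MDH2 (malate dehydrogenase), CAT2 (carnitine acetyltransferase) and FBP1 (fructose bisphosphatase) changed by 4.43 ± 0.28, 3.01 ± 0.20, 1.65 ± 0.19 and 1.26 ± 0.17. The 2 that fell were ICL1 (isocitrate lyase, −0.91 ± 0.23) and ACS (acetyl-CoA synthetase, −0.99 ± 0.23). SDH1 (also named in later comparisons), ICL1 and ACS lie outside the rule for named genes here, were chosen after their values were seen and were not followed through the alternatives.

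Fatty acid synthesis genes moved the other way, with 7 of 9 falling and 1 rising, 8 adjusted over the list alone (camera adjusted p = 0.0268). FAS1 changed by −1.71 ± 0.23, FAS2 by −1.89 ± 0.22, and the ATP citrate lyase subunits ACL1 and ACL2 by −1.95 ± 0.27 and −2.52 ± 0.28. In glycolysis and hexose uptake, 8 of 14 genes rose and 1 fell, 9 adjusted over the list alone, and camera did not call the list (adjusted p = 0.0549), although it did without untreated replicate 3 (0.0499) or treated replicate 1 (0.0303). PGK1, GPM1 and FBA1, enzymes of lower and middle glycolysis, changed by 2.48 ± 0.21, 2.73 ± 0.25 and 2.24 ± 0.22, while the hexose transporter YHT1 fell 29.6-fold.

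The other lists changed in both directions or in few members in the wild type. In ergosterol synthesis 7 of 13 genes rose and 1 fell (8 adjusted over the list alone, camera adjusted p = 0.257), among them ERG6 (3.19 ± 0.30), ERG13 (2.37 ± 0.30) and IDI1 (−2.18 ± 0.35). In alkane and fatty alcohol oxidation 3 of 17 rose and 7 fell (10 over the list alone, camera adjusted p = 0.697), with the fatty aldehyde dehydrogenase HFD2 at 3.77 ± 0.25 and the cytochrome P450 ALK3 at −3.11 ± 0.31. Among 12 acyl-CoA ligases 3 rose and 2 fell (5 over the list alone, camera adjusted p = 0.697), including rises of 7.61-fold for AAL6 and 6.72-fold for AAL7. In glycerolipid assembly 2 of 9 rose and 1 fell (3 over the list alone, camera adjusted p = 0.813): the glycerol kinase GUT1 (2.55 ± 0.25), the sterol acyltransferase ARE1 (2.29 ± 0.34) and the acyltransferase SLC1 (−1.95 ± 0.21). Of 15 peroxins, 3 rose and 2 fell (4 over the list alone, camera adjusted p = 0.744), with PEX23, PEX29 and PEX13 at 1.88 ± 0.17, 2.41 ± 0.31 and 0.99 ± 0.22. Of 6 genes of the pentose phosphate and NADPH list, MAE1 rose and 2 fell (3 over the list alone, camera adjusted p = 0.744), one of them GND1 (−1.30 ± 0.25). Of 5 lipases 1 rose and 1 fell, LIP2, an extracellular lipase, by 7.06-fold (2 over the list alone, camera adjusted p = 0.813). Of 7 regulators 2 rose and 2 fell (4 over the list alone, camera adjusted p = 0.744), the falls being MHY1 (−2.44 ± 0.24) and POR1 (−1.02 ± 0.21). Of 8 tested mitochondrially encoded genes 1 rose (0 over the list alone in edgeR, 3 at an unadjusted p under 0.05, 3 with DESeq2, camera adjusted p = 0.744). The alkane, lipase, NADPH, peroxin and regulator lists had medians and means of opposite sign.

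Across all genes, 3563 of 6301 passed the test in the wild type, 1798 higher and 1765 lower with hexanoic acid, and 2312 of them changed at least 2-fold. Among genes outside the lists, YALI0_B06028g rose from 0.293 to 143.4 CPM and YALI0_C19822g from 3.25 to 808.5 CPM. YALI0_B23452g fell from 1323 to 2.52 CPM and YALI0_B10626g from 404.9 to 1.35 CPM. Scaling by total counts alone moved the median log2 change of all genes from −0.01 to −0.11.

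The second comparison asked how the mutant responds to the acid. At the preset correlation camera called the TCA cycle, beta-oxidation, glyoxylate and ergosterol lists higher, and none of them with an estimated correlation (adjusted p = 0.524 for each). The difference in response between strains was not called for the ergosterol list (adjusted p = 0.908). In the TCA cycle 8 of 12 genes rose and none fell, 8 adjusted over the list alone (camera adjusted p = 4.03e-05), with LSC2 at 1.11 ± 0.19, IDH1 at 1.23 ± 0.25 and IDH2 at 1.14 ± 0.23. In beta-oxidation 7 of 12 rose and 1 fell, 9 adjusted over the list alone (camera adjusted p = 0.000850). POX6, POX3 and the thiolase POT1 changed by 1.42 ± 0.23, 1.38 ± 0.28 and 1.77 ± 0.36, and the peroxisomal nucleotide carrier ANT1 by 1.48 ± 0.33. In ergosterol synthesis 6 of 13 rose and none fell, 8 adjusted over the list alone (camera adjusted p = 0.00506), with ERG10 at 1.12 ± 0.25 and ERG6 at 1.42 ± 0.33. In the glyoxylate list only 3 of 10 rose and 7 did not pass, 4 adjusted over the list alone (camera adjusted p = 0.0283): MDH2 (1.71 ± 0.22), CIT2 (1.74 ± 0.29) and CAT2 (1.57 ± 0.22).

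Acyl-CoA ligases AAL6 and AAL7 rose 11.6-fold and 7.83-fold in the mutant, FAT1 2.81-fold, and the transporter YHT1 fell 69.0-fold. The strongest responses outside the lists included rises of YALI0_B06028g (log2 6.56 ± 0.38) and YALI0_C19822g (4.75 ± 0.54) and falls of YALI0_B23452g (−6.62 ± 1.01) and YALI0_E23859g (−6.32 ± 0.28). For YALI0_C19822g the 2 untreated mutant libraries stood at 2.62 and 12 CPM, and for YALI0_B23452g at 31.7 and 449 CPM. The size of the change in these 2 genes therefore depends on single libraries. Of 9 fatty acid synthesis genes 1 passed in edgeR, the elongase ELO1 (0.61 ± 0.19), and adjusted over the list alone ACL2 passed as well, with a fall (−0.89 ± 0.29). At an unadjusted p under 0.05 there were 4, and 3 passed with DESeq2 (camera adjusted p = 0.622). ELO1 was lost without untreated replicates 1 (0.70) or 2 (0.53) and treated replicates 1 (0.58) or 3 (0.51). It was also lost with total counts only (adjusted p = 0.0815), the stricter filter (0.0578), a fit to only the groups compared (0.0919) and a replicate block by title (0.0769) or description number (0.106). ACL2 passed over all genes without untreated replicate 2 (−1.30) and with the stricter filter (adjusted p = 0.0408) or DESeq2 (0.0153). The alkane, glycolysis and glycerolipid lists had medians and means of opposite sign. In total 1112 genes passed, 501 higher and 611 lower, with 735 at least 2-fold.

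Single libraries moved these mutant counts. The total was 447 without untreated replicate 1, 609 without treated replicate 2 and 674 without treated replicate 3. Without untreated replicate 1 the beta-oxidation list (adjusted p = 0.0536) and the glyoxylate list (0.132) were not called, nor were IDH1 (0.96), IDH2 (0.91), POX3 (1.03), ANT1 (1.25), FAT1 (1.19) and ERG6 (1.48, log2 change in each case). The glyoxylate list was also lost without treated replicate 3 (0.0541) and with a replicate block by title number (0.0796), ERG6 without untreated replicate 2 (1.37), and ERG10 without that library (0.98). A fit to only the groups compared lost IDH2 (0.0511), POT1 (0.0515) and FAT1 (0.0548, adjusted p in each case).

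Across genes, the log2 changes of both strains correlated (Pearson r = 0.604, Spearman rho = 0.559, 6301 genes, which are not independent replicates), and these 2 contrasts share no library. Of 911 genes called in both strains, 865 changed in the same direction, where independent lists of these sizes would give 314.1, and 46 changed in opposite directions (314.7 for independent lists). Over the genes called in the wild type, the median absolute log2 change was 1.24 in the wild type and 0.449 in the mutant. That choice of genes favours larger wild-type values. Pearson r was 0.447 without untreated mutant replicate 1.

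**Figure D3:**
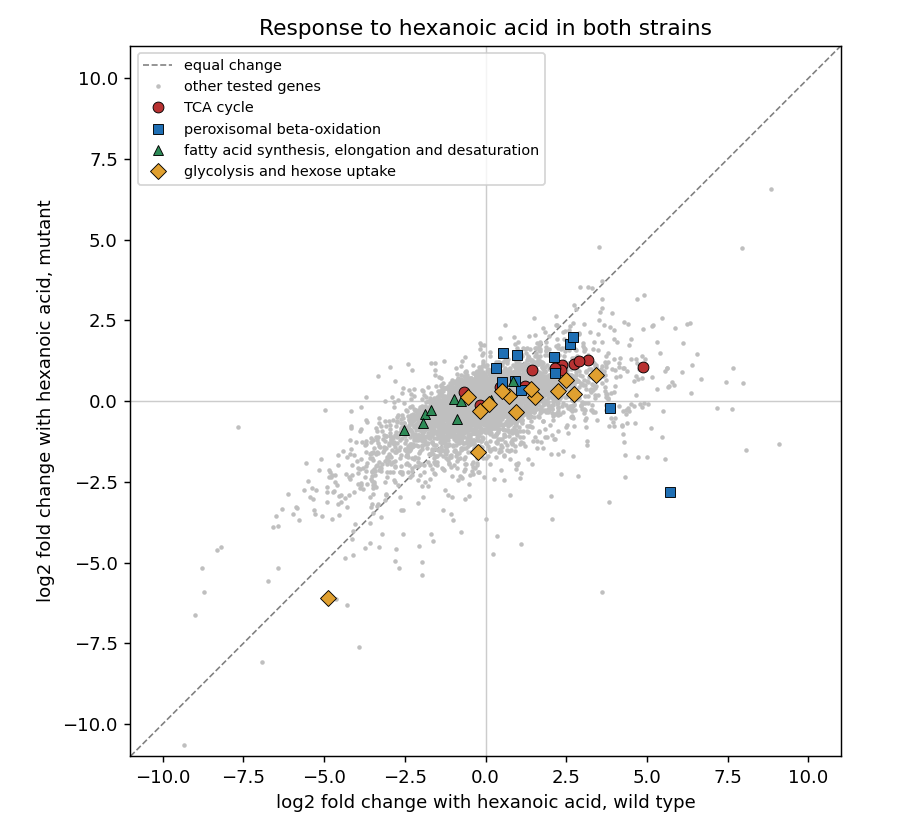
Log2 fold change with hexanoic acid in the wild type (x axis) against the mutant (y axis) for 6301 tested genes (grey points), with 4 gene lists marked and a dashed line of equal change. MDH1 of the TCA cycle lies at 4.89 on the x axis and 1.04 on the y axis, and CTA1 of beta-oxidation at 5.72 and −2.83.

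The third comparison asked how the strains differ without hexanoic acid. The untreated mutant already carried higher levels of several genes that hexanoic acid raised in the wild type. MDH1 was at 1844 ± 95.9 CPM (n = 2) against 127.3 ± 26.1 (n = 3), 14.5-fold higher, MAE1 was 26.3-fold higher and CIT2 7.02-fold higher. In the TCA cycle list 8 of 12 genes were higher, and adjusted over the list alone 9 passed, the added one being SDH1, which was lower (−0.72 ± 0.27), with CIT1 3.74-fold higher and IDH2 at 1.62 ± 0.22. This was the only list called (camera adjusted p = 0.00228), and it was not called with an estimated correlation (adjusted p = 0.892).

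Other lists were mixed in the untreated mutant. In glycolysis 6 of 14 genes were higher and 1 lower (7 adjusted over the list alone), including GPM1 (2.17 ± 0.26). In the glyoxylate list 5 of 10 were higher and 2 lower (7 over the list alone), with MDH2 at 1.57 ± 0.21 and the isocitrate lyase ICL1 at −1.29 ± 0.26. Beta-oxidation had 2 genes higher, POX5 (2.04 ± 0.31) and CTA1 (3.78 ± 0.67), and 3 lower, among them ANT1 (−1.97 ± 0.34), of 12 (7 over the list alone). POX5 stood at 109.8 and 251.3 CPM in the 2 untreated mutant libraries, against 36.2 to 53.1 CPM in the untreated wild type. The size of its strain difference, and of its response difference below, therefore depends on single libraries. Of 15 peroxins, 6 were lower and 2 higher (9 over the list alone), with PEX11 at −1.16 ± 0.22, the import receptor PEX5 at −0.86 ± 0.20, PEX23 at 1.22 ± 0.18 and PEX29 at 1.93 ± 0.33. No fatty acid synthesis gene passed in edgeR, over all genes or adjusted over the list alone (0 of 9, with 2 at an unadjusted p under 0.05), nor with DESeq2 (0).

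Further differences in the untreated mutant included AAL10 (5.57-fold higher), HFD2 (5.92-fold higher), ERG6 (5.41-fold higher) and GUT1 (2.63-fold higher). FAT1 was 3.21-fold lower, LIP2 6.68-fold lower, ALK3 7.75-fold lower, MHY1 4.07-fold lower and SLC1 2.58-fold lower. Outside the lists, YALI0_C11165g stood at 19980 ± 4574 CPM against 109.8 ± 114, and YALI0_F05016g was 145.3-fold higher. YALI0_E27247g was 32.3-fold lower and YALI0_A06974g 11.2-fold lower. The acyl-CoA ligase, NADPH and beta-oxidation lists had medians and means of opposite sign. In total 2402 genes passed, 1437 higher and 965 lower, with 1505 at least 2-fold. The total was 1375 without untreated mutant replicate 2, 71.7% of them higher against 59.8% with all libraries.

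The fourth comparison asked how the strains differ in the presence of the acid. MDH1 was at 3802 ± 223 CPM in the mutant and 3761 ± 460 in the wild type. Of 12 TCA cycle genes 1 passed, also adjusted over the list alone, KGD2 (a subunit of oxoglutarate dehydrogenase), which was lower in the mutant (log2 −0.63 ± 0.17). That call was lost without mutant replicates 1 (−0.54), 2 (−0.68) or 3 (−0.66) and wild-type replicates 2 (−0.57) or 3 (−0.56), and with total counts only (adjusted p = 0.0904), no filter (0.0517), a fit to only the groups compared (0.0535) and a replicate block by title (0.0794) or description number (0.0715). Several fatty acid synthesis genes were higher and several beta-oxidation genes lower in the mutant. FAS1 stood at 3136 ± 179 CPM in the mutant against 1131 ± 218 in the wild type (2.77-fold), FAS2 was 2.84-fold higher, and ACC1, acetyl-CoA carboxylase, 2.45-fold higher. POX5 was at 154.6 ± 14.2 CPM against 631.3 ± 123, and POX3 and CTA1 were 2.83-fold and 27.4-fold lower.

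In the fatty acid synthesis list 5 of 9 genes were higher and none lower, 5 adjusted over the list alone, and in beta-oxidation 6 of 12 were lower and none higher, 9 adjusted over the list alone (camera adjusted p = 8.68e-06 for both lists). Alkane and fatty alcohol oxidation had 5 of 17 higher and 1 lower, 6 over the list alone (camera adjusted p = 0.00520), with ALK5 4.75-fold and the aldehyde dehydrogenase HFD1 2.14-fold higher. Ergosterol synthesis was called with 1 of 13 genes higher, ERG10 at 2.05-fold, 2 over the list alone (camera adjusted p = 0.00296). The regulator list was called lower with 0 of 7 genes passing in edgeR over all genes, 4 at an unadjusted p under 0.05, 3 with DESeq2 and 4 adjusted over the list alone (camera adjusted p = 0.0270). With an estimated correlation the adjusted p was 0.174 for fatty acid synthesis, beta-oxidation and regulators, 0.177 for the alkane list and 0.358 for ergosterol. Peroxins had 1 higher and 2 lower of 15 (5 over the list alone), with PEX6 at 2.03-fold higher. The lipase list had a median and a mean of opposite sign, and the TCA list a positive median (0.03) and mean (0.01) with a downward test (adjusted p = 0.923).

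In total 673 genes differed with acid, 315 higher and 358 lower in the mutant, with 339 at least 2-fold. Scaling by total counts alone gave 677 genes, 422 higher and 255 lower, and moved the median of all genes from 0.03 to 0.16. Outside the lists, YALI0_C11165g (log2 4.73 ± 0.77) and YALI0_E05819g (3.22 ± 0.43) were higher, and YALI0_F19712g (−3.98 ± 0.74) and YALI0_E14256g (−3.69 ± 0.43) lower in the mutant.

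The count with acid depended on single libraries. It was 172 without mutant replicate 2, 223 without mutant replicate 3, 217 without wild-type replicate 2 and 134 without wild-type replicate 3. The regulator list was lost without mutant replicate 2 (adjusted p = 0.0558). ERG10 was lost without mutant replicate 3 (log2 0.82) and without wild-type replicates 2 (0.96) and 3 (0.95), and PEX6 without wild-type replicate 3 (0.94).

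The fifth comparison tested the difference between the responses of the strains. Several TCA cycle and glycolysis genes had a lower response to acid in the mutant, and several fatty acid synthesis genes a more positive one. In the TCA cycle list 7 of 12 genes had a lower response (camera adjusted p = 0.00437), with MDH1 at −3.84 ± 0.30 and CIT1 at −1.91 ± 0.34. Adjusted over the list alone 9 passed, among them SDH1 with a more positive response (0.97 ± 0.35). In glycolysis 7 of 14 had a lower response and none a higher one, 7 over the list alone (camera adjusted p = 0.0121), with GPM1, FBA1 and PGK1 at −2.51 ± 0.35, −1.93 ± 0.31 and −1.84 ± 0.30. In fatty acid synthesis 5 of 9 had a more positive response and none a more negative one, 5 over the list alone (camera adjusted p = 0.0301), with FAS1 at 1.42 ± 0.34, FAS2 at 1.49 ± 0.32 and ACL2 at 1.62 ± 0.41. With an estimated correlation each of these lists had an adjusted p of 0.741. The fatty acid synthesis call was lost without untreated mutant replicate 2 (adjusted p = 0.0832) and without untreated wild-type replicate 3 (0.0694), and with a replicate block by description number (0.0526). Beta-oxidation had 3 of 12 genes with a lower response, 4 over the list alone, and was not called (camera adjusted p = 0.133), although it was without untreated mutant replicate 1 (0.0129) or treated wild-type replicate 1 (0.0211).

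The response difference of CTA1 was −8.55 ± 0.92, as it rose in the wild type and fell from 28.6 ± 11.7 to 4.03 ± 0.56 CPM in the mutant. MAE1 (−5.22 ± 0.33), POX5 (−4.07 ± 0.43), HFD2 (−3.55 ± 0.34) and CIT2 (−2.69 ± 0.36) also had lower responses in the mutant. ALK5 (3.57 ± 0.40), LIP2 (3.45 ± 0.68) and ALK3 (3.12 ± 0.46) had more positive ones. With acid these genes fell in the wild type (log2 −2.41, −2.82 and −3.11). In the mutant their log2 changes were 1.16, 0.63 and 0.01, of which only that of ALK5 passed. The acyl-CoA ligase, ergosterol and peroxin lists had medians and means of opposite sign, and the regulator list a negative median and mean with an upward test (adjusted p = 0.908). In total 1604 genes differed in response, 630 with a more positive and 974 with a more negative change in the mutant, 1344 of them by at least 2-fold. The number of lists called did not set the true groups apart. Regroupings of the same 6 libraries that mix conditions called up to 4 lists for hexanoic acid in the wild type, where the true groups gave 4. Regroupings that mix strains called up to 7 for mutant against wild type with acid, where the true groups gave 5. Mixed regroupings keep part of the real difference between their groups, so these are not counts of false calls.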

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

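All tests of explanations in this part, except the counts over regrouped libraries, were chosen after the results were seen. The difference between the responses of both strains was tested as an interaction in edgeR, and 1604 genes passed. Named genes with a lower response in the mutant were CTA1 (−8.55), MAE1 (−5.22), POX5 (−4.07), MDH1 (−3.84), HFD2 (−3.55), PEX29 (−2.76), ARE1 (−2.70), CIT2 (−2.69), GPM1 (−2.51), PCK1 (−2.07), GUT1 (−2.05), FBA1 (−1.93), CIT1 (−1.91), MLS1 (−1.91), PGK1 (−1.84), ERG6 (−1.76) and MFE1 (−1.29), as log2 differences. Those with a more positive response were ALK5 (3.57), LIP2 (3.45), ALK3 (3.12), IDI1 (1.9), SLC1 (1.77), ACL2 (1.62), MHY1 (1.60), FAS2 (1.49), FAS1 (1.42) and ACC1 (1.04). All of these fell with acid in the wild type. A positive value here means a weaker fall or no called fall in the mutant, or, for ALK5, a rise. Lists that differed were the TCA cycle (adjusted p = 0.00437), glycolysis (0.0121) and fatty acid synthesis (0.0301) at the preset correlation, and none of them with an estimated correlation (0.741 for each). The fatty acid synthesis call was also lost without untreated mutant replicate 2 (0.0832) and untreated wild-type replicate 3 (0.0694), and with a replicate block by description number (0.0526). PCK1 lost its call without untreated mutant replicate 2 (−0.78), treated mutant replicates 1 (−1.79) and 3 (−2.02), untreated wild-type replicates 1 (−2.09), 2 (−1.99) and 3 (−2.13) and treated wild-type replicates 2 (−1.99) and 3 (−1.87), and with total counts only (adjusted p = 0.0546) or a replicate block by description number (0.11). ACC1 lost it without untreated mutant replicate 2 (0.99), treated mutant replicates 2 (1.07) and 3 (0.91), untreated wild-type replicate 3 (0.97) and treated wild-type replicates 2 (0.93) and 3 (1.01), and with a replicate block by title (adjusted p = 0.0724) or description number (0.0666), and IDI1 lost it without untreated mutant replicate 2 (1.54).

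The untreated mutant differed from the untreated wild type along the wild type's response to hexanoic acid. Fold changes of these contrasts correlated across genes (Pearson r = 0.767), and 2055 genes were called in both, 1186 higher in both (410.1 for independent lists), 829 lower in both (270.3) and 40 in opposite directions (677.9). Both contrasts use the same untreated wild-type libraries, and 20 simulations with no effect gave a mean r of 0.445 and a covariance of 0.0473, against an observed covariance of 1.323, a difference of 1.28. With no untreated wild-type library in common, r was at least 0.684, which argues against shared controls as the whole cause, although part of the excess overlap may come from them. A common shift would move all genes by the same part of their acid response, as at an earlier or later point in growth. It did not account for everything: 811 or more genes departed at each part tried, from 0 to 1 in steps of 0.1. The fatty acid synthesis list had a mean log2 change of −1.076 with acid in the wild type and 0 between the untreated strains. Its mean log2 distance from the common line (slope 0.5728) was 0.6167, at percentile 94.78 of 10000 matched random lists. Most random lists lay between −0.2693 and 0.7687. That range takes in a list that did not move, so this test cannot decide whether the list followed the shift. The count of departing genes was added after that percentile was seen. An effect of the mutation or the plasmid and a difference in culture state at collection both stay open and were not tested, because each strain was sampled from its own cultures.

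The libraries labelled mutant still held PEX10 reads. Wild-type cells or RNA making up 39.98% of the untreated mutant libraries would keep every gene at or above that share, but 34 genes of at least 10 CPM lay below it by more than 2 standard errors of the difference. With acid 30 genes lay below the PEX10 share of 45.2%, among them CTA1 at 3.66% of the wild-type level. An earlier form of this test found 1 gene: it asked for the same genes in both conditions and used the standard error of the gene alone, not that of the difference. For scale, 4882 genes reached 10 CPM in both wild-type groups, and how many would lie below the share by chance was not tested. The test bears on wild-type material as the source of all remaining PEX10 reads, not on a smaller admixture. A mislabelled library is also argued against, since DGA1 in the lowest mutant library was 13.25 times that of the highest wild-type library. Reads from parts of the locus left by the deletion, or from overlapping transcripts, cannot be told apart here from reads of an intact gene (39.98% of the wild-type level without acid), because counts per gene hold no position and the strand setting is not given in the sources used here.

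The response to hexanoic acid was smaller in the mutant. Fewer untreated mutant libraries do not explain the count, since the wild type still gave at least 3323 genes with 2 of its 3 untreated libraries, against 1112 in the mutant. The slope of the mutant response on the wild-type response over all tested genes was computed with wild-type responses that share no library, so that neither a choice of genes nor noise in the wild-type values lowers it. It lay between 0.323 and 0.379 with both untreated mutant libraries. With untreated replicate 1 alone it was 0.413 to 0.466, and with replicate 2 alone 0.225 to 0.291. Both ranges argue against 1 such library as the cause of the smaller response, but its size depends on the library used. A first form over genes called in the wild type, which favours a slope under 1, gave 0.351 and at most 0.427. One candidate explanation is that the untreated mutant already holds part of the response, since libraries of both strains with acid reached similar positions on the first principal component. The response difference is the strain difference with acid minus that without, so the shifted untreated mutant and the smaller response rest on shared libraries. The mean log2 strain difference of the TCA cycle list was 1.09 without and 0.008 with acid. Its smaller response thus lay in the untreated state. For fatty acid synthesis it was 0 and 0.84, so by these means its difference lay in the treated state. A strain difference with acid is not covered by this explanation. Whether this list also followed the shift without acid could not be decided by the test above. That explanation, differences in acid uptake or use between the strains, and culture state at collection were not otherwise separated by these data.

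Splits of the 6 wild-type libraries into 3 and 3 are too few (10) for a share under 0.05. The true split called 3563 genes and the highest of the others 0 (1 split as high). Mixed splits, here and by strain below, put both kinds of library in each group. The real difference then adds to the spread within groups, which lowers their gene counts in advance. These low gene counts are therefore no support for the true split. For lists, the true split called 4 and the highest of the others 4, so 2 of the 10 splits gave as many. Splits of the 6 libraries with acid by strain are equally few: the true one called 673 genes, the highest of the others 6 (1 split as high), and for lists the true one called 5, the highest of the others 7, so 4 of the 10 splits gave as many. Mixed splits hold unequal numbers of each kind of library in their groups, so part of the real difference remains and can call lists. Their list counts are therefore not those of data without a difference. The other comparisons include the group of 2 libraries and were not split.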

How the results depend on the processing

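Among the followed genes, lists and main values, 0 reversed in direction in the alternatives run. Over all called genes, 1 reversed in the mutant and 1 between untreated strains without untreated mutant replicate 1, and 3 between untreated strains without untreated mutant replicate 2. Followed genes stayed on their side of the threshold in 911 of 1006 leave-outs and 1319 of 1367 other settings, and lists in 445 of 462 and 261 of 280. With an estimated inter-gene correlation camera called 0 lists in each of the 5 comparisons, with 1, 1, 0, 3 and 0 lists at an unadjusted p under 0.05. Genes changed in the mutant numbered 659 in a fit to only the 2 groups compared, and genes differing with acid 1057 with DESeq2. Without a filter on low counts the similarity of both responses was r = 0.4997 (rho = 0.496). PEX10 with acid was −1.03 with total counts only (adjusted p = 0.0666). The cause was not tested for these changes. The replicate numbers did not pair libraries: of 15 same-number pairs by either numbering, correlations of deviations from the group means ran from −0.455 to 0.366, with 2 over 0.1, and 4 (titles) and 3 (descriptions) of 11 libraries correlated best with their own number. With a replicate block, genes changed in the mutant numbered 739 (titles), genes differing with acid 391 (titles) and 409 (descriptions), and PEX10 with acid was −1.16 by descriptions (adjusted p = 0.0661). With libraries left out in turn, counts ran from 3049 to 3483 for acid in the wild type, 447 to 952 in the mutant, 1375 to 2255 for the strains without acid, 134 to 768 with acid and 1103 to 1631 for the response difference. List counts ran from 4 to 5, 2 to 5, 1 to 1, 4 to 7 and 2 to 5 in the same order. The low of 2 in the mutant and the high of 5 for the response difference both came without untreated mutant replicate 1. The similarity ran from r = 0.447 to 0.639 and rho = 0.435 to 0.591, PEX10 from −1.63 to −1.07 without and −1.36 to −0.89 with acid, and DGA1 from 3.98 to 4.27 and 4.58 to 5.38. The median gene had a mean of 572 reads per library. Of simulated 2-fold differences in response 7% were recovered where 200 genes changed. That share is not the sensitivity of the real comparison, in which 1604 genes passed. No test separated depth from replicate number as a limit.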

Other observations

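Cytochrome P450 and fatty aldehyde genes for alkane use moved in both directions with hexanoic acid. ALK5 fell in the wild type (log2 −2.41 ± 0.27) and rose in the mutant (1.16 ± 0.29), ALK9 fell in both (−4.72 ± 0.72 and −2.81 ± 0.72), and ALK6 rose in both (1.88 ± 0.35 and 1.59 ± 0.38). The ALK5 rise in the mutant was not called without untreated replicate 1 (1.25), untreated replicate 2 (1.07) or treated replicate 3 (0.92), and a fit to only the groups compared lost ALK5 (adjusted p = 0.0542) and ALK6 (0.0924) in the mutant. These genes were chosen after their values were seen, and ALK9 was not followed through the alternatives.

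YALI0_C11165g was the most abundant gene in 4 of the 5 mutant libraries, with 0.992% to 2.81% of all counts, against 0.003% to 0.109% in the 6 wild-type libraries. In the marker genes of strain construction, AXP1 stood at 10.1 to 11.7 CPM in all 4 group means, LEU2 fell with acid in the wild type (−0.88 ± 0.24), and KU70 was higher in the untreated mutant (1.05 ± 0.28), and none of these was followed through the alternatives. The noncoding RNAs RPR1 and SCR1 reached 29.5 and 24.5 CPM in untreated wild-type replicate 2, against 6.69 and 5.82 CPM in replicate 3. Group means of RPR1 were 14.4 and 3.89 CPM in the wild type without and with acid, and 4.89 and 2.55 CPM in the mutant. The group means of SCR1, SNR14, SNR17 and SRN19 were likewise lower with acid in both strains. They were also lower in the untreated mutant than in the untreated wild type. Means of SNR17 were 18.5 and 13 CPM in the wild type and 11.3 and 7.09 CPM in the mutant, without and with acid. Without untreated wild-type replicate 2 the mean of that group was 6.87 CPM for RPR1 and 6.22 CPM for SCR1, the latter against 6.09 CPM with acid. It was then 16.7 CPM for SNR17 (13 with acid), 2.16 for SRN19 (1.01 with acid) and 2.08 for SNR14 (1.99 with acid). Whether library preparation moved with the groups was not tested. Of genes changed in both strains in opposite directions, 46 in number, 34 rose in the wild type and fell in the mutant and 12 did the reverse.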
